A study of Panagrellus redivivus with 189 samples.

How the data were processed

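Single blastomeres of embryos of the nematode *Panagrellus redivivus* were collected by hand after removal of the egg shell. They were profiled with CEL-Seq2, per the labels' protocols. CEL-Seq2 is a 3′-end RNA sequencing method in which each cell receives a barcode and each captured molecule a short random identifier before linear amplification. Per the labels, the barcoded cells of 1 embryo were pooled into 1 sequencing library, so embryo and sequencing library are the same unit. The values analysed are the raw counts that the authors deposited, 1 whole number per feature and blastomere, with no normalization. CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3 are named per the submitters' processing notes, without their roles. The genome build is not given in the sources used here. Nor is it stated whether counts are of reads or of distinct identifiers, and the closing section returns to this point.

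The copy of the count table used here holds 189 columns and 1572 complete rows and ends inside a further row, of which 130 fields are present. The rows carry no gene identifier. A deposited list of 24249 gene models on 940 scaffolds was read, but nothing pairs a row with a gene model, so features are named here by their row number in the table. The complete rows number 6.48% of the gene models. Further rows were not analysed here, and column totals are totals of the rows used, not library depths. For the same reason the lists of orthologues, complexes and cell type markers of *Caenorhabditis elegans* fixed in advance could be matched to 0 rows, and no gene function is given.

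Each column was assigned to its sample through the sample number in the description. All 189 columns were assigned. Stage came from the developmental stage label. The embryo, and the cell name where one was given, came from the title. The blastomeres of an embryo are not replicates of a condition, so counts were summed over the blastomeres of an embryo and the embryo was the replicate. This gave 20 embryos of 13 stages. Many sums cover part of an embryo, since there are fewer libraries than cells. The 8-cell embryos have 3 to 7 libraries and the 6-cell embryo has 4. Deep libraries also weigh more, as in 8-cell embryo 5, where 1 library held 41962 of 56246 counts. Most stages have 1 embryo, so 4 phases were formed from the stage labels: 1-3 cell (5 embryos, 9 blastomere libraries), 6-10 cell (9 embryos, 57 libraries), 12-20 cell (4 embryos, 50 libraries) and gastrula (2 embryos, 73 libraries). The 2 numbered 2-cell libraries were treated as 1 embryo, which the labels do not state. The phases, tests, named-feature rule and first set of alternatives were fixed before the data were examined.

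Sample numbers fall into a lower series (1 to 39, 39 libraries of 8 embryos) and a higher series (201 to 350, 150 libraries of 12 embryos). The series was treated as a candidate batch. All 5 embryos of the 1-3 cell phase are in the lower series and both gastrula embryos are in the higher series. The 6-10 cell phase has 1 lower and 8 higher embryos, and the 12-20 cell phase 2 and 2.

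Total counts per library over the rows used ranged from 299 to 46827 (median 6075), and detected features from 19 to 816 (median 465). Of the 1572 rows, 197 held no count. No pair of libraries had identical values. The embryos of a stage with the closest counts, the 2 1-cell embryos, differed by a chi-square of 2.84 per degree of freedom over 219 features, so no embryo was counted as a repeat of another. Intervals and floors cover counting error only. A floor is 3 counts over a group, and intervals have a level of 95%.

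Phases were compared with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with TMM scaling and the filterByExpr filter. All 20 embryos were in 1 fit with phase as the only factor, and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. The p-values measure the spread between these embryos, and the labels do not say whether embryos came from separate cultures. The named AB and P1 cells, and the cells named P4 or DP4 and the rest of their embryos, were compared in the same way with 2 sums against 2. Each AB and P1 pair, and each P4 cell with the rest, comes from the same embryo. The correlation of deviations within embryos was 0.376 for AB and P1 and 0.107 for P4, so the fit with the embryo as a block was run as well. Named features are the 2 largest rises and 2 largest falls past the threshold with a mean of at least 50 CPM in the higher group. CPM is the count scaled to a fixed total over the rows used, after TMM scaling.

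Values per cell were taken after thinning each library to 5000 counts. This left 114 libraries in 18 embryos and left out 75 libraries. Detected features were the expected number at that depth. Similarity was the Spearman correlation between libraries of an embryo with at least 3 such libraries, averaged over 5 thinnings. Features without a count in any of the compared libraries were left out. Correlations with stage order used 100000 permutations, or all permutations below 10 embryos, and all p-values are two-sided.

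Alternatives were DESeq2 1.42.0, DESeq2-type size factors in edgeR, no filter, the series as a term or fits within 1 series, libraries of at least 5000 counts, leaving out each embryo, other thinning depths and other measures. Further alternatives, named as such in the closing section, were chosen after seeing the data. Set tests used camera in limma 3.58.1.

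The steps were tested on simulated data drawn from the observed means and library sizes. For the comparison of the 6-10 cell and 1-3 cell phases, 200 of 577 features were changed. The test recovered 52.0% of 4-fold and 100% of 16-fold changes, with 3 false calls. For the 12-20 cell and 6-10 cell phases it recovered 64.0% and 98.0% of 577 features' simulated changes. For gastrula and 12-20 cell it recovered 27.0% and 90.0%. With 2 sums against 2, recovery was 14.3% and 92.9% for AB and P1 (171 features, 56 changed) and 6.25% and 81.3% for P4 (98 features, 32 changed). The real P4 library of the 14-cell embryo had only 26 detected features, which simulated means do not reproduce. Recovery for P4 may so be overstated.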

Results

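The data are counts of blastomere libraries, 39 of a lower and 150 of a higher number series, from 20 embryos of *P. redivivus*, a free-living nematode, from the 1-cell stage to late gastrula. The title of the series describes a characterization of embryogenesis cell by cell. The questions addressed are how RNA content changed between successive phases, whether named lineages differed, and whether cells of an embryo became less alike. Total counts over the rows used ranged from 299 to 46827 per library. Sums per embryo ranged from 5412 (8-cell embryo 3) to 396493 (late gastrula). The lower number series had a median of 4428 counts and 267 detected features per library. The higher series had 7130.5 counts and 505.5 features.

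The 2 number series differed in composition. In the lower series the highest count of any feature in any library was 1024, with 4 values at 1024 and 22 from 1000 to 1024. In the higher series 37 values in 27 libraries lay above 1024, up to 2780. A set of 6 feature rows (789, 955, 956, 1147, 1149 and 1177) held a median of 72.3% of the counts of a lower-series library (range 23.1% to 99.6%) and 5.09% of a higher-series library (range 1.43% to 33.2%). These rows were chosen after seeing the data, as those above 10 counts in each of the 3 libraries with fewer than 50 detected features. All 3 of those libraries belong to the 14-cell embryo, and 1 of them is the cell named P4.

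**Figure D1:**
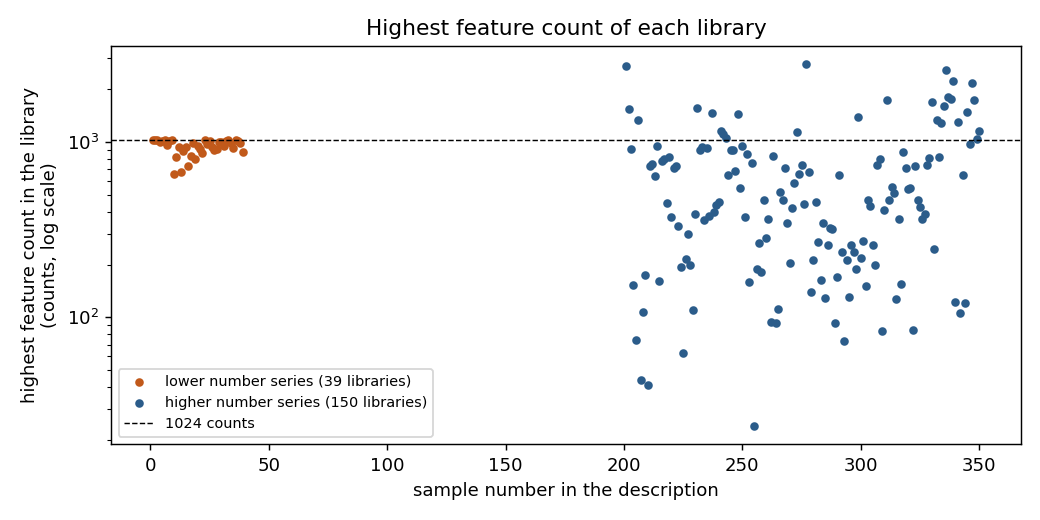
Highest feature count (counts, log scale) of each library against the sample number in its description, with 1 point per library and a dashed line at 1024 counts. The 39 lower-series libraries end at 1024, and 27 of the 150 higher-series libraries lie above it.

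Between the 1-3 cell and the 6-10 cell phase, feature rows 539 and 1534 went from no count in 5 embryos to among the abundant features, and rows 1130 and 722 fell. Row 539 had 0 counts in the 1-3 cell embryos and 5680 ± 2499 CPM (SD, n = 9) in the 6-10 cell embryos, at least 175.03-fold higher against a floor of 3 counts over the group. Row 1534 had 0 counts and then 4877 ± 3655 CPM (SD, n = 9), at least 150-fold higher. Row 1130 fell by 5.95 on the log2 scale (SE 0.73), from 1186 ± 556 CPM (SD, n = 5) to 26.1 ± 42.7 CPM (SD, n = 9). Row 722 fell by 5.20 (SE 0.55), from 6090 ± 3194 CPM (SD, n = 5) to 178.3 ± 156.2 CPM (SD, n = 9). By edgeR's quasi-likelihood test the adjusted p-values were 7.68e-07, 4.72e-06, 6.11e-07 and 2.87e-07 in that order.

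In all, 424 of 577 tested features passed the threshold between these phases, 312 higher in the 6-10 cell embryos and the rest lower. The median feature rose by 2.18 on the log2 scale, and by 2.56 with the other size factors. Over all features with a count it rose by 1.77 in edgeR without the filter and by 0.16 in DESeq2. Relative to the median, 276 of the called features were higher and the rest lower. Phase and series overlap here, since every 1-3 cell embryo is in the lower series. With the series as a term 202 features were called (37 of them lower), 190 of them among the 424, and the median rise was 1.01. Within the lower series, where 8-cell embryo 1 is the lone 6-10 cell embryo, 81 of 330 features were called (44 higher, 37 lower), 64 of them among the 424, and the median change was 0. The 4 named features kept their direction and passed the threshold with the series term. Within the lower series the direction was the same, but rows 539 and 1534 rest on 4 and 2 counts in 8-cell embryo 1, and that lone embryo is assumed to vary like the 1-3 cell and later embryos. There row 539 rose by 4.94 and row 1534 by 3.98 on the log2 scale, both less than over all embryos, with adjusted p-values of 0.00139 and 0.0441 by edgeR's quasi-likelihood test, while row 722 fell by 3.48.

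8-cell embryo 1 stood apart from the other 6-10 cell embryos in several of these features. It had 4 counts of row 539, or 226 CPM, against 4736 to 8837 CPM in the other 8 embryos. Row 722 was at 565 CPM, against 50.996 to 208 CPM. Later embryos of the same series did not share these levels of row 539, which was at 4978 CPM in 12-cell embryo 1 and 8040 CPM in the 14-cell embryo. Without 8-cell embryo 1, 467 features were called between the 1-3 cell and 6-10 cell phases.

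**Figure D2:**
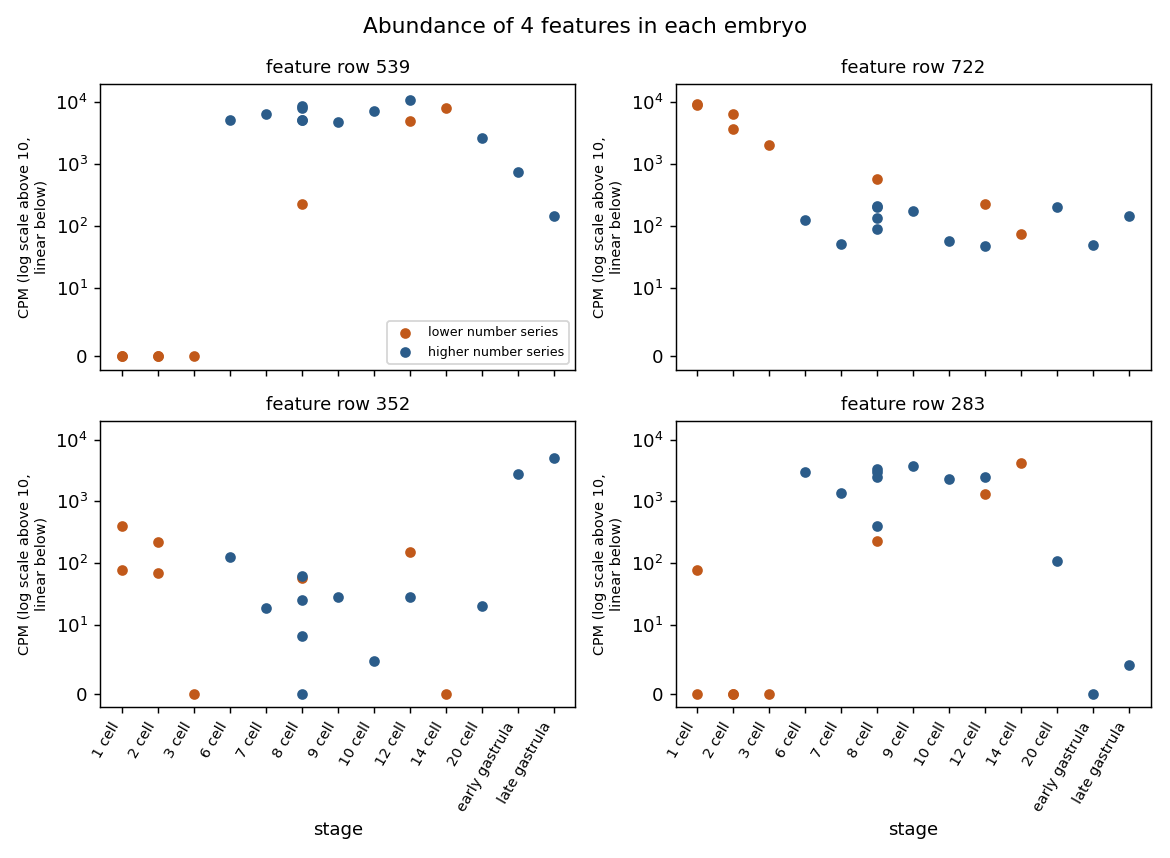
Abundance in CPM (log scale above 10, linear below) of feature rows 539, 722, 352 and 283 against stage, with 1 point per embryo coloured by number series. Row 539 is at 0 in the 5 embryos of 1 to 3 cells and at 226 CPM in 8-cell embryo 1, and row 352 is highest in the 2 gastrula embryos.

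Between the 6-10 cell and the 12-20 cell phase, no feature of 577 passed the threshold in edgeR's quasi-likelihood test, while 45 had an unadjusted p under 0.05. DESeq2 also called 0 features. The median change was -0.01 on the log2 scale. In the simulation, where 200 of 577 features were changed at once, 4-fold differences were found in 64% of cases. With fewer changed features the adjusted threshold is stricter, so the share found in the real comparison may be lower. Within the higher series (8 embryos against 2) 0 of 662 features were called. Within the lower series 56.4% of 330 were called, 70 of them lower and the rest higher, but there the 6-10 cell phase is 8-cell embryo 1 alone, so the calls describe that embryo. These fits within a series were added after seeing the data. The change between these phases differed between the series for 21.3% of 667 features by an interaction term in edgeR, which rests on the same embryo. Without it 8 features were called between the phases.

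Between the 12-20 cell phase and gastrula, rows 585 and 352 rose and rows 208 and 283 fell. Row 585 had 0 counts in the 4 embryos of 12 to 20 cells and 885 ± 551 CPM (SD, n = 2) in the gastrula embryos, at least 98.7-fold higher. Row 352 rose by 6.80 on the log2 scale (SE 1.09), from 49.2 ± 67.3 CPM (SD, n = 4) to 3862 ± 1567 CPM (SD, n = 2). Row 208 had 778 ± 525 CPM (SD, n = 4) and then 0 counts, at least 169.3-fold lower. Without the late gastrula embryo the log2 change was -9.004, against -9.32 with both gastrula embryos, but no longer passed the threshold (adjusted p = 0.174, edgeR's quasi-likelihood test). Row 283 had 2029 ± 1752 CPM (SD, n = 4) and then 2 counts in both gastrula embryos together. The ratio of its group sums was 348, with a counting interval of 95.6 to 2884. The adjusted p-values by edgeR's quasi-likelihood test were 4.34e-04, 4.34e-04, 0.00448 and 8.63e-04. Rows 208 and 283 were already at 104.5 and 109.5 CPM in the 20-cell embryo, against at least 804 and 1337 CPM in the 3 embryos of 12 or 14 cells.

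In this comparison 42 of 577 features passed the threshold, 16 higher and 26 lower in gastrula. With the series as a term 64 were called (20 higher, 44 lower) and within the higher series, in an added fit, 45 (9 higher, 36 lower). Gastrula is represented by 1 early and 1 late embryo. The count fell to 6 without the late gastrula embryo and to 19 without the early one, to 23 without 12-cell embryo 2, and rose to 70 without the 20-cell embryo. It was 95 with DESeq2, 87 without the filter and 22 with libraries of at least 5000 counts.

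The first division gives the anterior AB cell and the posterior P1 cell, the germline precursor. These cells are named in 1 2-cell pair and in the 3-cell embryo. No tested feature passed the threshold between AB and P1 in edgeR's quasi-likelihood test, and 0 had an unadjusted p under 0.05. With the embryo as a block 0 were called, with 3 unadjusted. DESeq2 called 0. With 2 sums against 2, simulated 4-fold differences were found in 14.3% of cases, so most differences of that size would have been missed.

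P4 is the name of a later germline precursor in nematode embryos. The cell named P4 in the 14-cell embryo had 2508 counts, of which 98.9% came from the 6 rows named above, and 26 detected features. The labels do not say what DP4 is, and it was grouped with P4 by its name. The cell named DP4 in 12-cell embryo 1 had 4085 counts and 340 features. Against the rest of their embryos, 1 of 98 features passed the threshold in edgeR's quasi-likelihood test. This was row 479, higher by 3.56 on the log2 scale (SE 0.91) with an adjusted p of 0.0128. Its 30 counts in the named cells came from the 12-cell library. The call so rests on 1 library, and with the embryo as a block no feature passed.

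Features detected per library at 5000 counts differed between the series. In the lower series embryo medians ran from 257 to 330 in 7 embryos, and in the higher series from 433 to 514 in 11 embryos. The 6 dominant rows take up more of these counts in the lower series, which leaves fewer for the other features. At 2000 counts without these rows, chosen after seeing the data, the ranges overlapped, with 236 to 340 in 7 and 325 to 391 in 12 embryos. Over the 18 embryos, Pearson's r with stage order was 0.555 (permutation p = 0.0182) and Spearman's rho was 0.437 (permutation p = 0.0702, adjusted p = 0.140 over 2 relations). Without the 2 embryos farthest from the median stage r was 0.548. At 2000 counts, with all 20 embryos, r was 0.266 (permutation p = 0.258) and rho 0.0880 (permutation p = 0.714). At 2000 counts without the 6 rows r was 0.565 (permutation p = 0.0120) and rho 0.402 (permutation p = 0.0887). Within the series the relation differed. In the higher series the Spearman correlation with stage order was -0.578 (permutation p = 0.0678) and Pearson's r -0.506 (permutation p = 0.114), or -0.545 without the 2 farthest embryos. At 2000 counts without the 6 rows the Spearman correlation there was -0.598 (permutation p = 0.0425). In the lower series the Spearman correlation was 0.382 (exact permutation p = 0.394) and Pearson's r 0.805 (exact permutation p = 0.0413), or -0.642 without the 2 farthest embryos. At 2000 counts without the 6 rows r was 0.904 (exact permutation p = 0.0198), or -0.637 without the 2 farthest embryos, and the Spearman correlation 0.546 (exact permutation p = 0.219).

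Over 13 embryos, libraries of an embryo did not become measurably less alike with stage. Each embryo's value is over the features counted in its own libraries. There were 3 such libraries in the 3-cell embryo and 29 in late gastrula, so the feature set may change with stage. An effect of this on the relation was not tested. The mean Spearman correlation between libraries of an embryo ran from 0.542 (14-cell embryo) to 0.823 (10-cell embryo) over 13 embryos. Its relation to stage order had a Pearson's r of -0.0646 (permutation p = 0.844) and a Spearman's rho of -0.00552 (permutation p = 0.993, adjusted p = 0.993 over 2 relations), and without the 2 farthest embryos r was -0.242. In the higher series rho was 0.322 (permutation p = 0.361, n = 10). The lower series has 3 such embryos, too few for a correlation with stage. Their values fell with stage, from 0.796 in the 3-cell embryo to 0.697 in 8-cell embryo 1 and 0.542 in the 14-cell embryo. The 6 dominant rows held 60.5%, 86.3% and 62.9% of the counts in the 3 libraries of the 14-cell embryo. In those of the 3-cell embryo they held 23.1% to 40.8%. Whether these rows account for the fall was not tested. Without them at 2000 counts the 3-cell embryo was the only lower-series embryo left. Over the 13 embryos, with Pearson correlation of log2 CPM as the measure, rho was 0.602 (permutation p = 0.0337), towards more alike libraries. Of all 40 late gastrula libraries, 21 have a digit in the title that may be a number of cells, as does 1 of 17 20-cell libraries. If so, their similarity and detected features are not those of single cells. Neither relation to stage was fitted without these libraries.

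**Figure D3:**
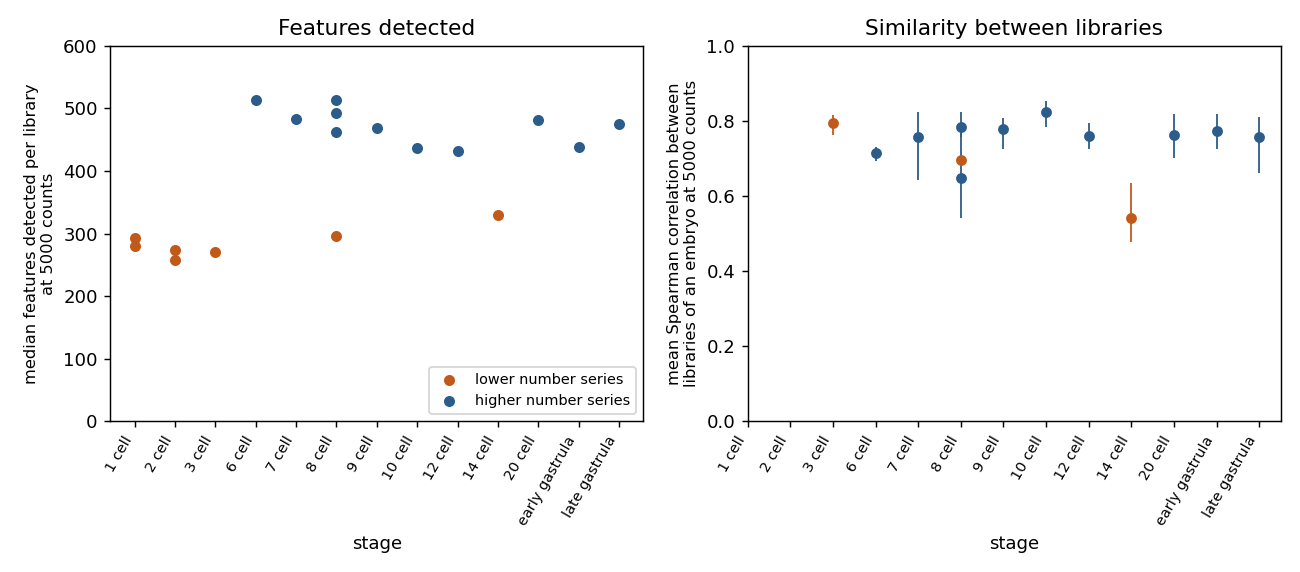
Left, the median number of features detected per library at 5000 counts; right, the mean Spearman correlation between libraries of an embryo at 5000 counts, with bars from the lowest to the highest pair; both against stage with 1 point per embryo. The lower-series embryos lie between 257 and 330 detected features and the higher-series embryos between 433 and 514.

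At the 8-cell stage, libraries of the same embryo were more alike than libraries of different embryos. Over 15 libraries of 4 embryos the mean Spearman correlation was 0.769 within embryos (25 pairs) and 0.572 between embryos (80 pairs). The difference of 0.196 had a permutation p of 1e-05, the smallest that 100000 permutations can give. Pairs of different embryos averaged 0.397 across the series and 0.715 within the higher series. Without 8-cell embryo 1 the difference was 0.0573 (permutation p = 0.00115). Without 8-cell embryo 4 it was 0.221 (permutation p = 0.00460), but this came from the series. Pairs within embryos then averaged 0.713, pairs of different higher-series embryos 0.711, and pairs across the series 0.395. The higher series alone was not fitted without embryo 4, so a difference inside that series may rest on this embryo. Each embryo was 1 sequencing library, so embryo and library batch cannot be told apart.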

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

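The values below were singled out because 1 embryo lay far from the others of its phase or stage, or because a change differed between the number series. Of 34 sets of 4 to 10 embryos tested, 12 had such an embryo. How many chance would give was not measured, since the sets share embryos and several of the values rest on few counts. All tests of explanations in this part were chosen after the results were seen.

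The onset and decay features used here are those that rose or fell between the 5 embryos of 1 to 3 cells and the 2 embryos of 12 and 14 cells within the lower series, among 279 tested without the 6 dominant rows (edgeR, adjusted p under 0.05). Of the 21 ways to pick 2 of these 7 embryos, only the real one called as many as 226 (54.4% of them rising). The highest of the others called 0, though each of these mixes early and late embryos in 1 group. With 21 ways the result cannot be rarer than 1 in 21, so chance is argued against only at that level. 8-cell embryo 1 took no part in the choice.

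8-cell embryo 1 had a log2 ratio of onset to decay counts of -1.76, against 1.63 to 3.16 in the other 8 embryos of 6 to 10 cells and 1.63 to 2.80 in the other 4 8-cell embryos. The 1-3 cell embryos had -3.04 to -2.55. Its detected features at 5000 counts were 296, against 438 to 514 in the other 6-10 cell embryos with a library of that depth. This value lies within the 257 to 330 of the lower series, so it says nothing on the embryo apart from its series. Its CPM of row 539 was 226 (4 counts) against 4736 to 8837. Of row 722 it was 565 (10 counts) against 50.996 to 208 in the phase and 87.4 to 208 among 8-cell embryos, but 2055 to 9211 in the 1-3 cell embryos. Row 1130 did not follow, with 0 counts in 8-cell embryo 1 against 306 to 1765 CPM in the 1-3 cell embryos. The change from the 6-10 cell to the 12-20 cell phase differed between the series for 21.3% of 667 features by an interaction term. 8-cell embryo 1 is the lone lower-series embryo of the first phase.

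For the position of 8-cell embryo 1, the number series alone was tested on later embryos and stays open at 8 cells. The 2 later lower-series embryos, placed with features chosen without each of them, had log2 ratios of 3.28 and 3.77. That of 8-cell embryo 1 was -1.68 or lower. The lower series so need not give a low ratio at 12 or 14 cells. The features were chosen with the other of these 2 embryos, though, so high ratios were likely. Few counts are argued against, since the onset share of 8-cell embryo 1 was 17.1% with a Wilson upper limit of 17.8%. This lies below the 54.8% of the lowest other 8-cell embryo. RNA of 1-3 cell embryos mixed into its libraries stays open. Judged by decay shares in a mixture with 12-14 cell RNA, it would have to make up 81.9% of the counts outside the dominant rows. Row 722, at 565 CPM (10 counts), and row 1130, at 0 counts, were below all 1-3 cell embryos. They were picked as the largest falls and have few counts, so they do not decide. The 7 libraries of 8-cell embryo 1 all had ratios between -2.47 and -1.56. A wrong stage label is argued against if its 7 libraries are of 1 embryo and the series does not shift the ratio. The other 13 embryos of at least 7 cells had ratios of 1.63 or more. Of these, 12-cell embryo 1 and the 14-cell embryo helped to choose the features, and the others are in the higher series. Libraries of several embryos under 1 name, or an embryo that switched later relative to its divisions, may account for it as well, and neither was tested.

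A second pattern is the end of lower-series counts at 1024, which is the number of different identifiers of 5 bases. A candidate explanation is that lower-series counts are of distinct 5-base identifiers, which cannot exceed 1024 for a feature. The 25 values up to 1024 held 22 counts, the 25 values before them 10, and the 25 values after them 0. A first test of 22 against 0 was dropped, since the 0 drew attention to the pattern. Setting 22 against 10, tried after it, gave an exact binomial p of 0.0501, and these values come from 3 feature rows in 14 libraries, so it does not decide. A test on 1 count per library, tried next, argues against lower depth, or a shift in composition, as the whole cause. Row 1177 had 14 of its 39 lower-series counts within 25 of its highest. Under the mixture of Poisson means that fits its counts best, a median of 3 was drawn, and as many as 14 with p = 0.000900 after multiplying by the 3 features tested. For row 789 (7 counts) this p was 0.161 and for row 1147 it was 1. The 7 libraries whose highest count was 1023 or 1024 had totals from 5394 to 18696. If identifiers were counted, high counts in the lower series understate abundance, and how identifiers were counted in the higher series stays open.

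The third pattern is the 424 features called between the 1-3 cell and 6-10 cell phases. Of 100 splits of these embryos, 1, the real one, called as many, so chance is argued against at that level. The highest other called 22.7% of the tested features. The 6 dominant rows are argued against as the cause, since 421 features were called without them, 382 of these among the 424. The 81 features called within the lower series do not decide on the series as the whole cause, since the later phase is 8-cell embryo 1 alone there. Nor does the 94.3% of 212 features called in the same direction between 1-3 and 12-14 cells of the lower series, since both comparisons share the 1-3 cell embryos. A further test used the 4 embryos of 12 to 20 cells, 2 of each series, which lie outside the contrast. In the direction of their change, the 421 features differed between the series there by a median of 0.19 on the log2 scale (quartiles -0.32 and 0.83). Their change from the 1-3 cell to the higher-series 6-10 cell embryos had a median of 3.32 (quartiles 2.24 and 4.85). This argues against the series as the whole cause, provided that the series acted alike in both phases. The series may still account for part of the count, since the series term left 202. How much is series and how much is phase cannot be told apart where no 1-3 cell embryo is in the higher series.

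Between the 6-10 cell and 12-20 cell phases the real split called 0 features. Any split calls at least as many, as all 100 did, so the splits say nothing about chance here. The highest other called 82, which points to structure among these embryos other than phase.

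The other values were as follows. Row 283 was at 76.8 CPM (1 count) in 1-cell embryo 1 and at 0 in the other 4 embryos of 1 to 3 cells. Row 352 was at 125.7 CPM (3 counts) in the 6-cell embryo, against 0 to 60.99 CPM. Row 585 was at 7.05 CPM (1 count) in the 9-cell embryo and at 0 in the other 8. Row 1130 was at 132.6 CPM in 8-cell embryo 3, against 0 to 48.8 CPM, which is 1 count against up to 8. These 4 values rest on too few counts to set an embryo apart. Row 1534 was at 12917 CPM in 8-cell embryo 2, against 113.04 to 6245 CPM, and at 9367 CPM in 12-cell embryo 2, against 980 to 1932 CPM in the other 3 embryos of 12 to 20 cells.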

How the results depend on the processing

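Fits within a series for the 2 later phase comparisons, and those without the 6 dominant rows or the near-empty libraries, were chosen after seeing the data. The cause of a change was not tested unless given. For 6-10 cell against 1-3 cell, 20 of 24 alternatives stayed within 1.5 times of 424. The others called 202 (series term), 198 (series term, without the 6 rows), 81 (lower series) and 90 (lower series, without the 6 rows), the last 2 with fewer embryos. Leaving out 1 embryo gave 389 to 467. For 12-20 cell against 6-10 cell, 21 of 26 called 0. As percent of tested features, no filter gave 1.89%, the series term 0.173%, the lower series 56.4%, and 61.6% without the 6 rows. Leaving out 1 embryo gave 0 to 1.38%. For gastrula against 12-20 cell (42), DESeq2 gave 95, no filter 87, the series term 64, libraries of at least 5000 counts 22, and leaving out 1 embryo 6 to 70. For P4 (1), the replicate block gave 0, the other size factors 2, DESeq2 2, no filter 0, without the 6 rows 6, and leaving out 1 embryo 0 to 2. Row 479 was at 3.84 without the 14-cell embryo and at -5.97 without 12-cell embryo 1, where the P4 library left is near empty and the median feature was at -7.65, so the sign says nothing. AB against P1 gave 0 in 8 of 8, the replicate block included, which says little at a recovery of 14.3% for 4-fold changes. For AB and P4, leaving out 1 embryo leaves 1 sum against 1, with the spread taken from all 4 sums.

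Of the alternatives for 9 named features, 4 lost the call (row 208 without the late gastrula embryo, and row 479 with the block, DESeq2 and no filter), 1 changed sign (row 479, as above) and all others kept direction and call. Detected features against stage reversed within the higher series, to -0.578, and to -0.598 there without the 6 rows at 2000 counts. The rho of similarity with stage, -0.00552, turned positive in 6 of 6: 0.0776 at 2000 counts, 0.0719 at 10000 counts, 0.602 with Pearson correlation, 0.162 without the 6 rows at 2000 counts, 0.322 in the higher series and 0.514 there without the 6 rows at 2000 counts. The 8-cell difference stayed past the threshold in 9 of 9 (0.0457 to 0.309), though several of these keep the contrast between the series.

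The 8-cell and 12-cell embryos share the numbers 1 and 2, which mark embryos within a stage and pair nothing per the labels. Deviations of embryos with the same number correlated at 0.290, where number 1 is also the lower series. The replicate block called 0 features, as did the same embryos without it.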

Other observations

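All tests in this part were chosen after the results were seen.

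Placed on the onset and decay features, the higher-series embryos lay near the later lower-series embryos that helped to choose the features. The lone lower-series embryo that took no part in the choice, 8-cell embryo 1, did not, with an onset share of 17.1%. Onset features held 8.74% to 11.5% of counts, without the 6 dominant rows, in the 5 embryos of 1 to 3 cells, and decay features 66.7% to 72.1%. In the higher series, which took no part in choosing the features, onset features held 52.4% in the 6-cell embryo and 63.9% in the 7-cell embryo. They held 54.8% to 63.97% in the 4 8-cell embryos and 64.6% to 65.3% in the 9-cell and 10-cell embryos. Decay features held 16.6% and 8.70% in the 6-cell and 7-cell embryos. 12-cell embryo 2 of the higher series had an onset share of 65.9% and 12-cell embryo 1 of the lower series, which helped to choose the features, 67.3%. The onset share was 56.6% in the 20-cell embryo, 51.7% in early and 47.8% in late gastrula. No embryo of 4 or 5 cells was analysed here. All embryos of 1 to 3 cells are in the lower series, so when the onset share rose cannot be told apart from the series.

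Within the higher series, without the 6 dominant rows, 197 of 612 features changed with stage order from 6 cells to late gastrula (82 fell, the others rose; edgeR, adjusted p under 0.05). Row 1025 went from 0 CPM in the 6-cell and 7-cell embryos to 450 ± 370 CPM (SD, n = 2) in gastrula, and row 614 from 4914 ± 4747 CPM (SD, n = 2) to 0. Of 100 orders of the 12 embryos, 2 called as many, the real one included. This argues against chance at that level but does not exclude it. The highest other order called 272, more than the real one. That points to structure among the embryos other than stage. Of the tested features 32.2% were called with all embryos, 11.8% without the late gastrula embryo and 20.1% without the early one. The hypothesis that the same features move alike in the lower series was not borne out but stays open, because that series spans 1 to 14 cells. Of the features that rose, 34 were measured there, with a camera p of 0.519 with an estimated correlation. For the 19 that fell it was 0.455.

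Titles of 21 of the 40 late gastrula libraries and 1 of the 17 20-cell libraries have a digit before the blastomere number. The hypothesis that the digit is the number of cells in the library was tested on total counts in late gastrula. Titles without a digit counted as 1. Spearman's rho over these libraries was 0.480 (permutation p = 0.00233) and Pearson's r with log2 counts was 0.436 (permutation p = 0.00526), or 0.372 without the 2 libraries farthest from the median. These are libraries of 1 embryo, not independent samples. Median counts were 5388 without a digit (19 libraries), 10672 with a 2 (7 libraries), 17674 with a 4 (11 libraries) and 17635 with a 6 (2 libraries), and 2215 in the lone library with a 3. Adding up the digits gives 92 cells where titles begin with 100, and 19 cells where they begin with 20. These values go with the hypothesis. Digits stand mostly on the higher blastomere numbers, and an effect of that order, which the labels do not explain, was not excluded. Without the libraries that carry a digit, 52 features were called between gastrula and the 12-20 cell phase.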
